A study of Mus musculus with 14 samples.

How the data were processed

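RNA sequencing of sorted splenic regulatory T cells of mice was analysed from 14 tables, 1 per sequenced sample. Each table was an abundance table of kallisto, which assigns reads to transcripts without a genome alignment, run against a transcriptome of the mouse build GRCm38, per the submitters' processing notes. The version of kallisto and the annotation release were not given in the sources used here. The expected counts (estimated reads per transcript) were deposited by the authors without normalization, and they were fractional where a read fitted several transcripts. The TPM values were deposited by the authors too, per the file headers, and are scaled to the same total in each table by kallisto's effective transcript length. The lengths and effective lengths (other columns of the deposited tables) were the same in all 14 tables, with an effective length 199 bases below the length for long transcripts, so 1 fragment length had been used for every sample. The library kit did not keep the strand, per the labels' protocols, so reads of a gene and of an overlapping antisense gene cannot be told apart.

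The 88198 transcripts of the tables were matched by identifier to the GENCODE annotation of GRCm38 in the box. For 2079 transcripts no gene was found; they held between 1.17% and 1.28% of the reads of a sample and were left out. Estimated counts were summed over the transcripts of each of 30284 genes. Gene positions come from that annotation and are counted from 1.

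The titles give each sample a first number and a second number. The first number was taken as the unit of replication before the data were examined, because no label says that the second number is another animal. The 2 samples of a unit differed slightly more than sampling noise: the chi-square over genes per degree of freedom was between 1.44 and 1.90, and between 1.09 and 1.28 for genes with 1 transcript and no shared sequence. Between different units of a group the first value was between 7.37 and 108. The counts of the 2 samples were therefore summed and rounded to whole numbers, which left 4 control units and 3 units labelled as talin knockout. The labels state that a library came from 1 or 2 animals, but not which animals stand behind which number, so p-values measure the spread between these units, and that spread can be partly technical.

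Gene tests used edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter, a quasi-likelihood fit with robust dispersion and the group as the only term, and Benjamini-Hochberg adjustment at a false discovery rate (FDR) of 0.05. CPM values are counts scaled to the library size after TMM. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. The quoted n is 4 control and 3 knockout-labelled units throughout. The step was tested on simulated counts for this comparison with 15098 genes, of which 100 were changed 2-fold and 100 were changed 4-fold. It called 45% of the genes changed 2-fold and 70.7% of those changed 4-fold, and 7.2% of its 125 calls were on unchanged genes.

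Gene lists were written before the data were examined: 21 pathway lists and 7 lists of other cell types and RNA quality, each kind adjusted as a family. They were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01. In the simulation, camera gave a p of 6.28e-15 for a list of 25 genes shifted by 0.7 on the log2 scale. It gave 0.542 for an unshifted list. The simulated genes were drawn independently of each other, so this does not test camera on lists of correlated genes. An estimated correlation and fry were alternatives. A list of sex-linked genes was only described. Transcripts of Tln1 were compared with limma on log2(TPM + 1) among 34064 transcripts with a mean TPM of at least 1.

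The genes to be named were fixed by a rule written in advance. It takes Tln1. It takes the 8 genes with the largest rise and the 8 with the largest fall among genes past FDR 0.05 with a mean of at least 10 CPM and no overlap between the groups, leaving out pseudogenes, genes named only by number, and histone, immunoglobulin and T cell receptor segments. It also takes up to 4 members of each tested list with the smallest adjusted p, and Foxp3, Il2ra, Ctla4, Ikzf2, Itgb1, Itga4, Itgal, Itgb2 and Cd44 whatever their result. A pathway list, which was kept in the adjustment, and a gene of the rule are not reported here, and not every other gene that the rule takes is described. The sex-linked list gave no names because it had no test. Genes named outside the rule are marked as chosen after their values were seen, as are members that make up a list's count.

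Shared sequence was measured as the percentage of a gene's 31-base words that occur in another gene. The alternatives tried before the data were examined were DESeq2 1.42.0 size factors, upper-quartile and library-size scaling, 2 other count filters, the DESeq2 Wald test, limma-voom, glmTreat against a fold of 1.5, an FDR of 0.01, all 14 samples as replicates with and without the unit as a random block, either sample of a unit alone, an effective-length offset, the replicate number as a block, limma on log2 TPM with pseudocounts of 0.1, 1 and 5, and leaving out each unit in turn. Added after seeing the data were an offset for the trend on GC content and transcript length, summing of sequence families whose genes share at least 50% of their 31-base words, protein-coding genes only, a covariate for B cell and myeloid transcripts, and a fit without control unit 1 and knockout-labelled unit 3.

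Depth after summing was between 12851425 and 56109143 estimated reads per unit. A count of 3 reads corresponds to 0.236 CPM in the shallowest unit and 0.0531 CPM in the deepest, so differences below these levels were not detectable. The tables hold no reads, so splice junctions, sequence variants and deleted exons were not analysed here.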

Results

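Messenger RNA was measured in regulatory T cells sorted from mouse spleen by the Foxp3 and YFP signals. Regulatory T cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. In the control mice the Tln1 alleles were wild type, and in the knockout mice both Tln1 alleles were floxed; all mice were heterozygous for a Cre recombinase driven by Foxp3. Tln1 encodes talin-1, an adaptor that binds the tails of integrin beta chains and switches integrins to their active form. Foxp3 lies on the X chromosome, so a heterozygous female carries the Cre allele on 1 of its X chromosomes. The comparison asks what regulatory T cells express when talin, and with it integrin activation, is lost. The 14 sequenced samples formed 4 control units and 3 units labelled as knockout, with 12851425, 20863157, 39214264 and 13458684 estimated reads in control units 1 to 4 and 44524768, 38811489 and 56109143 in knockout-labelled units 1 to 3. In the values given here, the error of a CPM or TPM value is the SD between units and that of a log2 fold change is the SE, with n = 4 control and n = 3 knockout-labelled units.

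The total Tln1 signal was not lower in the knockout-labelled units. Tln1 (ENSMUSG00000028465; GRCm38 chromosome 4, 43531519 to 43562691, minus strand) was at 668 ± 128 CPM (SD, n = 4) in the control units and at 901 ± 113 CPM (SD, n = 3) in the knockout-labelled units. The log2 fold change of 0.43 ± 0.18 (SE) did not pass the edgeR test (adjusted p = 0.126), and its sign depended on the processing: it was -0.37 with an effective-length offset. The longest Tln1 transcript, ENSMUST00000030187, has 57 exons and 8393 bases. It carried most of the Tln1 reads and was at 68.5 ± 18.3 TPM in the control units against 89.5 ± 11.7 TPM. A processed Tln1 transcript of 283 bases, ENSMUST00000126078, overlaps exons 4 and 5 of the longest one (43555564 to 43555946). It was at 185, 9.86, 190 and 163 TPM in control units 1 to 4 and at 6.6, 4.92 and 1.81 TPM in knockout-labelled units 1 to 3. In control units 1, 3 and 4 it was thus above the longest transcript in TPM, which is scaled by length. In reads it was far below: the first sample of control unit 1 had 96.5 estimated reads of it and 3814 of the longest. Length-scaled values of the gene therefore weigh the short transcript far more than the CPM does. The short transcript's difference of -4.15 ± 0.99 (SE) in log2(TPM + 1) did not pass the limma test either (adjusted p = 0.0722). Control unit 2 was nearer to the knockout-labelled units than to the other control units. Which exons the loxP sites flank was not given in the sources used here, and transcripts that lack a few exons are still counted, so the gene total checks the labels only weakly. The units are called knockout-labelled for that reason, and every direction given here rests on the labels.

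**Figure D1:**
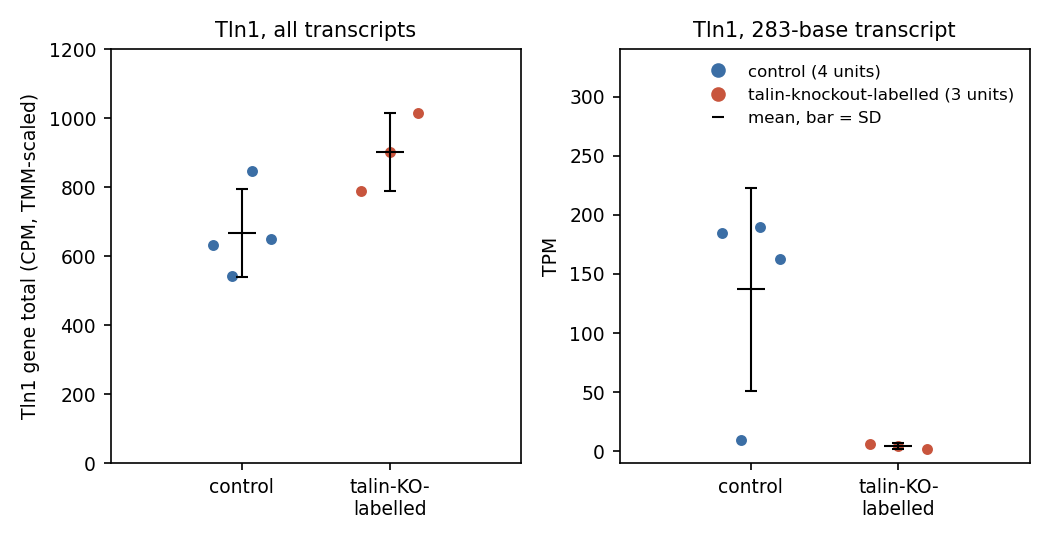
Left, the Tln1 gene total in TMM-scaled CPM per unit; right, the TPM of the Tln1 transcript of 283 bases; points are units, and bars give the mean and SD of 4 control and 3 knockout-labelled units. The gene totals have means of 668 and 901 CPM, and the short transcript lies at or below 6.6 TPM in the knockout-labelled units and at 9.86 TPM in 1 control unit.

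In the knockout-labelled units, 13 of 24 genes that mark regulatory T cells fell, 9 of 26 early response genes rose, and 11 of 20 B cell, 10 of 24 myeloid, 8 of 13 dendritic cell and 9 of 14 cytotoxic lymphocyte markers rose. As whole lists, only the first kept its camera call with an estimated correlation (adjusted p = 0.0203). The others were at 0.748, 0.126, 0.239, 0.126 and 0.303. With fry, the regulatory T cell, B cell, myeloid and dendritic cell lists passed (adjusted p = 0.000252, 0.00204, 0.0116 and 0.00204). The early response and cytotoxic lymphocyte lists did not (fry adjusted p = 0.0774 and 0.0713). Foxp3 itself was at 419 ± 71.0 CPM in the control units and 429 ± 76.1 CPM in the knockout-labelled units. Nt5e, which encodes the ectonucleotidase CD73, fell 2.24-fold, Nrp1, encoding the receptor neuropilin-1, fell 2.52-fold, and Egr1, a transcription factor gene induced within minutes of stimulation, rose 2.48-fold. Of 15775 genes tested with edgeR, 2144 changed: 1116 were higher and 1028 lower in the knockout-labelled units. More than 2-fold changes were mostly rises, with 846 genes higher and 286 lower. The groups did not overlap for 4863 genes, which is 30.8% against the 5.71% that chance gives. The median log2 fold change was -0.53 for genes under 40% GC and 0.37 for those over 55% GC. Against the mean of the units, genes under 40% GC were at 0.41, 0.19, -0.02 and 0.33 (log2) in control units 1 to 4. They were at -0.12, -0.23 and -0.51 in knockout-labelled units 1 to 3. Control units 1, 2 and 4 also had fewer reads than any knockout-labelled unit. Depth and group thus partly went together, and an effect of depth on the trend was not tested. Once the trend on GC content and transcript length was taken out, 1832 genes changed. The share of them that was higher went from 52.1% to 38.9%. Taking the trend out also shifted the log2 fold changes of all genes by a median of -0.20, which in itself lowers this share. Leaving out control unit 2 left 1122 calls, control unit 4 758, knockout-labelled unit 2 1131 and knockout-labelled unit 3 977. With a covariate for B cell and myeloid transcripts, which separated the groups, 16 genes passed. Of 92 called genes that the fixed rule names, 50 passed in every fit that left out 1 unit and 42 did not.

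The groups separated on the first principal component of the 500 most variable genes, which held 72.8% of their variance. The knockout-labelled units lay at 60.3, 46.5 and 78.7 on it. Control units 2 to 4 lay at -49.1, -59.4 and -63.3, and control unit 1 lay between the groups, at -13.8. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.939 to 0.963 within the control group, 0.953 to 0.976 within the knockout-labelled group and 0.857 to 0.930 between groups.

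The largest rises among the genes named by the fixed rule were Cpne4 and a set of granulocyte genes. Cpne4, a copine gene on chromosome 9 (104547286 to 105034544), had 3 reads in all control units and 3851 in the knockout-labelled units. The ratio was 787, with a 95% counting interval of 269 to 3820. This interval rests on reads pooled over the units of a group and leaves out the spread between units. Elane, Prtn3, Ctsg and Mpo encode proteins of the primary granules of neutrophil precursors; Mpo rose from 2.49 ± 2.38 CPM to 379 ± 477 CPM and Elane reached 78.4 ± 103 CPM. Knockout-labelled unit 3 held most of these means, with Mpo at 114, 94.0 and 930 CPM in units 1 to 3; without it the log2 fold change of Mpo went from 7.32 to 5.44 and that of Elane from 8.48 to 6.47. Mpo passed in 4 of the 7 fits that left out 1 unit, Elane in 3, Prtn3 in 4 and Ctsg in 6. The calls of Mpo and Prtn3 ended without control unit 2, 3 or 4, that of Elane without any 1 control unit and that of Ctsg without control unit 4. Ngp and Ltf, genes of later neutrophil granules, rose by 6.84 ± 1.27 and 6.70 ± 1.04 on the log2 scale, and Ngp passed in 2 of the 7 fits. St6galnac1, a sialyltransferase gene, rose by 6.94 ± 0.67 on the log2 scale, and 43.0% of its sequence words are shared with other genes. The largest falls were in Eps8l1 (log2 fold change -3.16 ± 0.73), Nrn1 (-2.19 ± 0.25), Dnah7a (-2.18 ± 0.25), the peptide transporter gene Slc15a2 (-2.12 ± 0.31), mt-Nd3 (-2.12 ± 0.32), the interferon-inducible gene Mndal (-2.03 ± 0.48), mt-Atp8 (-1.98 ± 0.34) and Gpm6b (-1.95 ± 0.24). Dnah7a, mt-Nd3 and Mndal share 54.2%, 98.1% and 27.0% of their sequence words with other genes, so their values are uncertain. Eps8l1 passed in 1 of the 7 fits that left out 1 unit, Mndal in 1 and mt-Atp8 in 6.

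Of the 24 genes of the regulatory T cell signature, 13 fell and 0 rose in edgeR, and 15 fell when adjusted over the list alone. The list's median log2 fold change was -0.71, and camera gave an adjusted p of 9.35e-09 for a fall; adjusted p = 0.0203 with an estimated correlation. Nt5e (chromosome 9, 88327197 to 88372092) went from 265 ± 19.9 to 118 ± 1.03 CPM (adjusted p = 0.000814) and Nrp1 (chromosome 8, 128358604 to 128503363) from 255 ± 35.6 to 101 ± 3.50 CPM (adjusted p = 0.000851). Tigit, an inhibitory receptor gene, fell by 1.65 ± 0.21 on the log2 scale, and Penk, the gene of the opioid precursor proenkephalin, fell by 1.90 ± 0.29. Il2ra, the alpha chain of the interleukin 2 receptor, went from 706 ± 38.1 to 373 ± 49.5 CPM (edgeR adjusted p = 0.0055). Ikzf2, which encodes Helios, went from 1113 ± 287 to 590 ± 188 CPM and was close to the threshold (edgeR adjusted p = 0.0491). Izumo1r, Tnfrsf4, Socs2, Plagl1, Klrg1, Ikzf4 and Itgb8 made up the rest of the genes that fell. Foxp3 did not pass the test (log2 fold change 0.03 ± 0.18, edgeR adjusted p = 0.923); its sign turned under other settings, to -0.38 with the GC offset. Ctla4, an inhibitory receptor gene, was at 657 ± 279 and 507 ± 124 CPM (edgeR adjusted p = 0.503). Ikzf2 passed in 0 of the 7 fits that left out 1 unit, Itgb8 in 1 and Socs2 in 5. With the covariate for B cell and myeloid transcripts, 1 of the 24 fell. In the same units, markers of B cells had a median log2 fold change of 3.08.

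**Figure D2:**
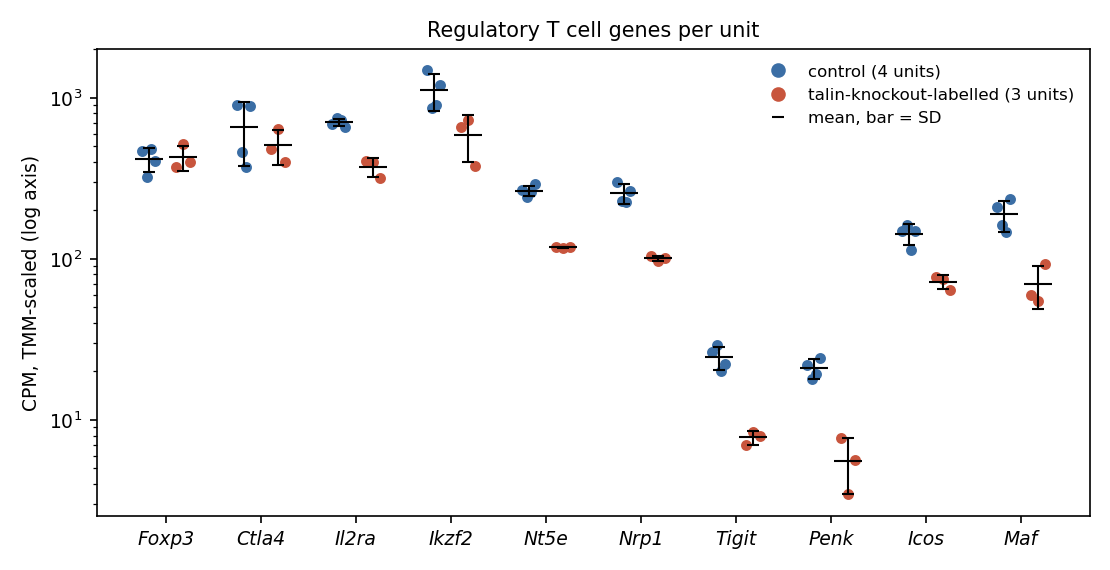
TMM-scaled CPM on a log axis for 10 regulatory T cell genes in each unit; points are units, and bars give the mean and SD of 4 control and 3 knockout-labelled units. Foxp3 has means of 419 and 429 CPM and Ctla4 overlaps between groups, while Nrp1, with means of 255 and 101 CPM, Nt5e and Tigit do not overlap.

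Among 30 genes of suppression and of effector regulatory T cells, 3 rose and 6 fell in edgeR, against 6 and 10 adjusted over the list alone. Icos, a costimulatory receptor gene, fell by 0.99 ± 0.15 on the log2 scale, Maf, a transcription factor gene, fell by 1.44 ± 0.23, and Pdcd1, which encodes PD-1, fell by 1.22 ± 0.22. Il10, the gene of an anti-inflammatory cytokine, Tnfrsf9 and Klrg1 fell too. Id2, a transcriptional inhibitor gene, rose by 1.13 ± 0.22, and Prf1 and Il12a rose at low level; Prf1, which encodes perforin, is also on the list of cytotoxic lymphocyte markers. The list as a whole did not pass camera (adjusted p = 0.12), with a median of -0.25 and a mean of 0.00. In the interleukin 2 and STAT5 list, 4 of 17 genes fell: Il2ra, Socs2, Socs1 and the survival gene Bcl2, with 0 rises; 5 fell and 2 rose adjusted over the list alone. Socs1 and Socs2 encode feedback inhibitors of cytokine signalling and fell by 0.83 ± 0.19 and 0.92 ± 0.19 on the log2 scale, and Bcl2 went from 604 ± 55.1 to 374 ± 49.3 CPM. Camera gave an adjusted p of 0.0424 for this list; adjusted p = 0.748 with an estimated correlation. Bcl2 passed in 5 of the 7 fits that left out 1 unit, Socs1 in 5 and Socs2 in 5. The list's call ended without control unit 2 (adjusted p = 0.0695), control unit 3 (0.147) or knockout-labelled unit 1 (0.071).

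Integrin genes moved in both directions. Of 20 integrin subunit genes, 3 rose and 3 fell in edgeR, against 6 and 4 adjusted over the list alone, and camera gave an adjusted p of 0.344. Itgae, the alpha chain that pairs with beta 7 and binds E-cadherin, fell from 31.5 ± 3.41 to 13.4 ± 2.62 CPM. Itgav fell by 0.83 ± 0.15 on the log2 scale and Itgb8, whose product pairs with that of Itgav to release active TGF-beta, fell by 1.52 ± 0.39. Itga5, a fibronectin receptor chain, rose from 13.2 ± 2.62 to 26.5 ± 4.87 CPM and Itga2b, a platelet chain, from 4.27 ± 0.501 to 13.7 ± 2.31 CPM. Itgam, a myeloid chain that shares 68.2% of its sequence words with other genes, also rose. Itgam is also on the list of myeloid markers and Itga2b on that of erythroid and platelet markers. The rises of these genes can therefore not be assigned to the regulatory T cells. The 4 subunits fixed in advance were not past the threshold: Itgb1 was at 288 ± 41.1 and 197 ± 34.6 CPM (edgeR adjusted p = 0.0556), Itga4 at 1651 ± 225 and 1385 ± 246 CPM, Itgal at 752 ± 94.3 and 719 ± 50.2 CPM and Itgb2 at 459 ± 60.6 and 460 ± 22.1 CPM. Among 32 measured adaptors and adhesion signalling genes, 4 rose (Vcl, Zyx, Flna and Skap2) and 2 fell (Lims1 and Rap1a), against 7 and 4 adjusted over the list alone. Vcl, which encodes vinculin, a partner of talin at adhesions, rose from 3.27 ± 0.447 to 23.6 ± 13.3 CPM, with 39.4% of its sequence words shared with other genes, and Zyx, encoding zyxin, from 92.3 ± 19.4 to 153 ± 15.8 CPM. Vcl was at 15.2, 16.6 and 39.0 CPM in knockout-labelled units 1 to 3, and in the same units the myeloid and the erythroid and platelet markers had median log2 fold changes of 3.48 and 5.03, with their highest means in unit 3. Rap1a, the gene of a small GTPase that recruits talin, fell by 0.78 ± 0.20 on the log2 scale. Camera gave an adjusted p of 0.344 for the adaptors too, and a median of 0.17 that turned to -0.08 with the GC offset. Itga5 passed in 6 of the 7 fits that left out 1 unit, Itgb8 in 1, Zyx in 4, Lims1 in 2 and Rap1a in 2.

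Of 26 early response genes, 9 rose and 0 fell in edgeR, against 11 and 1 adjusted over the list alone, with a median log2 fold change of 1.22. Egr1 (chromosome 18, 34859823 to 34864984) went from 81.5 ± 11.7 to 202 ± 15.9 CPM (adjusted p = 0.000851), and Zfp36, whose product destabilises cytokine messages, from 381 ± 59.4 to 995 ± 138 CPM. Ier2 rose from 67.4 ± 12.7 to 171 ± 40.5 CPM and Nr4a1, an orphan nuclear receptor gene induced by T cell receptor signals, by 2.22 ± 0.42 on the log2 scale. Fosl2, Dusp5, Btg2, Nfkbid and Nfkbia rose as well. Fos, chosen after its values were seen, was at 284 ± 259 and 1023 ± 300 CPM without passing the test. Camera gave an adjusted p of 6e-06 for this list; adjusted p = 0.748 with an estimated correlation. With the GC offset 4 of the 26 rose and 1 fell. The mean log2 CPM of the early response list was 6.85, 5.71, 5.54 and 7.06 in control units 1 to 4 and 7.49, 7.87 and 7.56 in knockout-labelled units 1 to 3. That of the list of heat shock and dissociation stress was 6.98, 5.70, 5.79 and 6.99 against 6.72, 7.17 and 7.74, so control units 1 and 4 were the higher control units on both lists. On the stress list Atf4 and Dnajb1 rose out of 17 genes, 0 fell, and 7 rose and 1 fell adjusted over the list alone. Its median was 0.55 and its camera adjusted p 0.0173; adjusted p = 0.748 with an estimated correlation, and the call ended without control unit 3 (0.0697) or knockout-labelled unit 3 (0.114). Of 26 T cell receptor signalling genes, the receptor chain gene Cd3g and the phosphatase gene Ptpn22 fell and 0 rose, with 1 fall adjusted over the list alone (camera adjusted p = 0.0698). Cd3e had a log2 fold change of -0.50 ± 0.15 (edgeR adjusted p = 0.0532). In the list of NF-kB and TNF receptor genes, Tnfrsf9 and Tnfrsf4 fell and Map3k14 and Nfkbia rose out of 23, with 3 falls and 4 rises adjusted over the list alone (camera adjusted p = 0.92). This list's median of 0.07 and camera's direction, down, differed in sign. Nr4a1 passed in 5 of the 7 fits that left out 1 unit, Ptpn22 in 5, Map3k14 in 5, Dnajb1 in 3, Cd3g in 2 and Nfkbia in 1.

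Of 28 interferon response genes, 9 fell in edgeR and 1 rose, against 13 and 1 adjusted over the list alone, with a median log2 fold change of -0.48. Rtp4 fell by 1.12 ± 0.18 on the log2 scale, Ifih1, which encodes the RNA sensor MDA5, fell by 0.66 ± 0.12, and Ifit2 went from 104 ± 6.11 to 59.6 ± 12.0 CPM. Ifit3 went from 31.9 ± 7.93 to 9.23 ± 2.43 CPM, but 61.8% of its sequence words are shared with other genes. Ifit1, Xaf1, Gbp2, Rsad2 and Usp18 fell too, and Irf1, an interferon-induced transcription factor gene, rose by 0.61 ± 0.13. Camera gave an adjusted p of 1.41e-06 for a fall; adjusted p = 0.748 with an estimated correlation. In the same units the B cell and myeloid markers had median log2 fold changes of 3.08 and 3.48. Of 20 TGF-beta pathway genes, Itgb8 and Itgav fell and the receptor gene Tgfbr3 rose, with the same counts of 2 and 1 adjusted over the list alone (camera adjusted p = 0.285). Tgfbr3 passed in 1 of the 7 fits that left out 1 unit and Itgb8 in 1.

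All 36 cell cycle genes had a log2 fold change above 0, with a median of 1.41, and 0 of them passed the edgeR threshold, over all genes or adjusted over the list alone; 16 had an unadjusted p under 0.05. Their mean log2 CPM was 4.85 and 4.47 in knockout-labelled units 1 and 2 and 6.59 in unit 3, against 3.59 to 4.74 in the control units. Cdk1, the kinase that drives mitosis, was at 5.29 ± 2.21 and 26.1 ± 25.6 CPM, and Aurka at 3.69 ± 1.06 and 17.6 ± 17.5 CPM. Camera gave an adjusted p of 1.11e-05; adjusted p = 0.748 with an estimated correlation. Knockout-labelled unit 3 also had the highest mean of the erythroid and platelet list, 7.70 against 3.83 and 2.99 log2 CPM in units 1 and 2.

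Of 23 cholesterol synthesis genes, 6 fell (Hmgcs1, Idi1, Cyp51, Stard4, Msmo1 and Sc5d) and 0 rose, also adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, went from 91.9 ± 16.9 to 52.7 ± 10.9 CPM. With the GC offset, 1 of the 23 passed. The median was -0.08 and the camera adjusted p 0.0424; adjusted p = 0.748 with an estimated correlation, and the call ended without control unit 2 (0.0763), control unit 3 (0.418) or knockout-labelled unit 1 (0.0626). Of 21 glycolysis genes, the kinase genes Pfkl and Hk2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0903). The median of 0.37 turned to -0.01 with the GC offset. No gene of the oxidative phosphorylation list, which matched 33 annotated genes, passed edgeR, also adjusted over the list alone, with 4 higher and 2 lower at an unadjusted p under 0.05, and camera gave an adjusted p of 0.908. Of 45 cytosolic ribosomal protein genes, 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.24). Rps7 and Rpl3, which fell by 1.83 ± 0.25 and 0.96 ± 0.24 on the log2 scale, share 61.0% and 35.7% of their sequence words with pseudogenes and other copies, and Rpl3 turned to 0.04 when near-identical copies were summed. Of 24 apoptosis genes, Bcl2, Xiap and Casp8 fell and Cdkn1a rose, against 4 and 3 adjusted over the list alone (camera adjusted p = 0.664); its median of 0.02 and camera's direction, down, differed in sign. Stard4 passed in 5 of the 7 fits that left out 1 unit, Xiap in 4, Cdkn1a in 4, Hmgcs1 in 3, Cyp51 in 3, Pfkl in 2, Hk2 in 2, Rpl3 in 2, Idi1 in 1 and Casp8 in 1.

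Homing genes and naive T cell markers changed in single members. Of 22 chemokine receptor and homing genes, Ccr1 and Cxcr6 rose and Cxcr5 and Ccr4 fell, against 3 and 3 adjusted over the list alone (camera adjusted p = 0.89). Cxcr5, the receptor that guides cells to B cell follicles, went from 37.3 ± 6.68 to 19.1 ± 1.13 CPM, and Cxcr6 from 7.62 ± 1.39 to 24.4 ± 12.7 CPM. Cxcr6 was at 32.2, 31.2 and 9.79 CPM in knockout-labelled units 1 to 3. The means of the CD8 T cell and NK cell markers there were 3.47, 3.09 and 2.14 log2 CPM. Ccr1 went from 0.293 to 3.82 CPM, and in the same units the myeloid markers had a median log2 fold change of 3.48. Cd44, an activation marker, was at 118 ± 12.8 and 133 ± 20.5 CPM (edgeR adjusted p = 0.458). Of 20 naive and central T cell markers, Klf2, a transcription factor gene that controls egress from lymphoid organs, rose from 242 ± 56.1 to 514 ± 126 CPM, and Bcl2 fell, also adjusted over the list alone (camera adjusted p = 0.205). Of 12 measured T helper cytokine and transcription factor genes, Tnfsf11, which encodes RANK ligand, and Lta fell and 0 rose, against 3 falls adjusted over the list alone (camera adjusted p = 0.25). Tnfsf11 went from 40.7 ± 10.1 to 11.8 ± 0.739 CPM. Lta passed in 4 of the 7 fits that left out 1 unit, Cxcr6 in 3 and Ccr4 in 3.

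**Figure D3:**
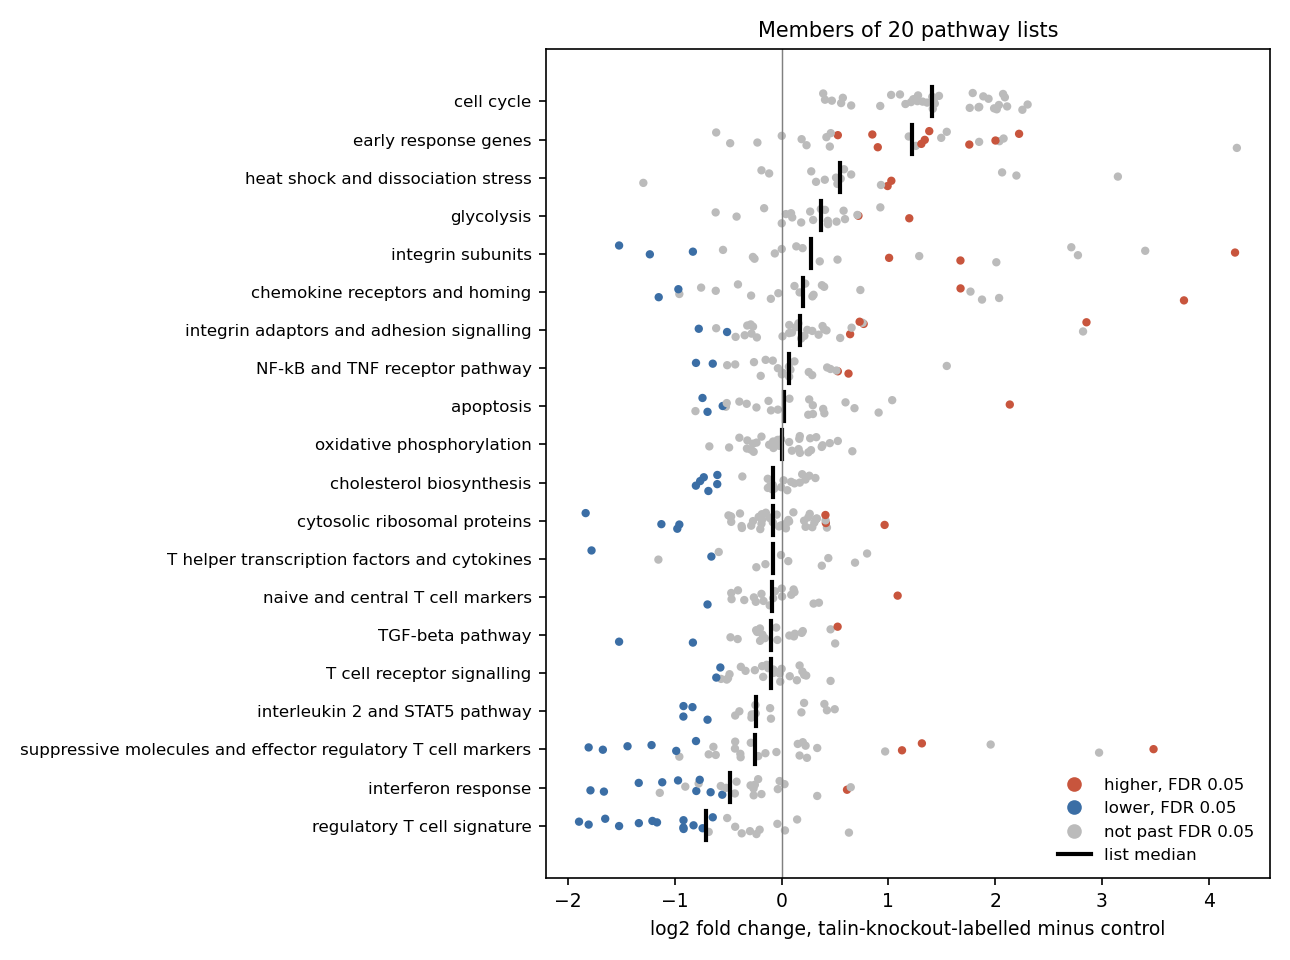
Log2 fold changes (knockout-labelled minus control, x axis) of the members of 20 of the pathway lists; each point is a gene, coloured by its edgeR call at FDR 0.05, and black bars are list medians. The regulatory T cell signature has the lowest median, -0.71, and the cell cycle list the highest, 1.41, with 0 genes past the threshold.

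Of 20 B cell and plasma cell genes, 11 rose and 0 fell in edgeR, against 19 and 0 adjusted over the list alone. Cd79a, a chain of the B cell receptor, went from 4.85 ± 1.75 to 52.0 ± 10.8 CPM (adjusted p = 0.000262), and Blk, Sdc1 and Cd79b rose as well. Of 24 macrophage, monocyte and neutrophil genes, 10 rose and 0 fell, against 15 and 0 adjusted over the list alone; Ly6c2, a monocyte surface gene, went from 8.12 ± 2.26 to 62.4 ± 33.6 CPM. Of 13 dendritic cell genes, 8 rose and 0 fell, against 12 and 0 adjusted over the list alone; Flt3, a growth factor receptor gene of dendritic cell precursors, rose by 4.72 ± 0.65 on the log2 scale and Irf8 from 22.1 ± 5.14 to 59.6 ± 13.6 CPM. Of 14 CD8 T cell and NK cell genes, 9 rose and 0 fell, against 11 and 0 adjusted over the list alone; Nkg7, a granule protein gene, went from 6.85 ± 1.36 to 21.6 ± 4.62 CPM. The medians of these 4 lists were 3.08, 3.48, 3.16 and 1.66, and camera gave adjusted p of 1.23e-13, 1.23e-13, 1.65e-07 and 0.000607. With an estimated correlation the adjusted p were 0.126, 0.239, 0.126 and 0.303, and with fry they were 0.00204, 0.0116, 0.00204 and 0.0713. Of 12 erythroid and platelet genes, Itga2b rose and 0 fell, against 10 and 0 adjusted over the list alone, with a median of 5.03 (camera adjusted p = 0.000937); adjusted p = 0.303 with an estimated correlation. Of 7 measured stroma and endothelium genes, Pdgfrb rose and 0 fell, with 1 rise adjusted over the list alone. This list did not pass camera (adjusted p = 0.121, and 0.3 with an estimated correlation) but passed fry (adjusted p = 0.00204). Only 1 of the 7 genes was at 1 CPM or more in the control units. Pdgfrb passed in 6 of the 7 fits that left out 1 unit. Immunoglobulin segments held 0.206%, 0.364%, 0.128% and 0.0574% of the reads of control units 1 to 4 and 1.86%, 1.02% and 2.98% of those of the knockout-labelled units; 50 of 192 rose and 0 fell. Of 193 T cell receptor segments, 14 fell and 1 rose.

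**Figure D4:**
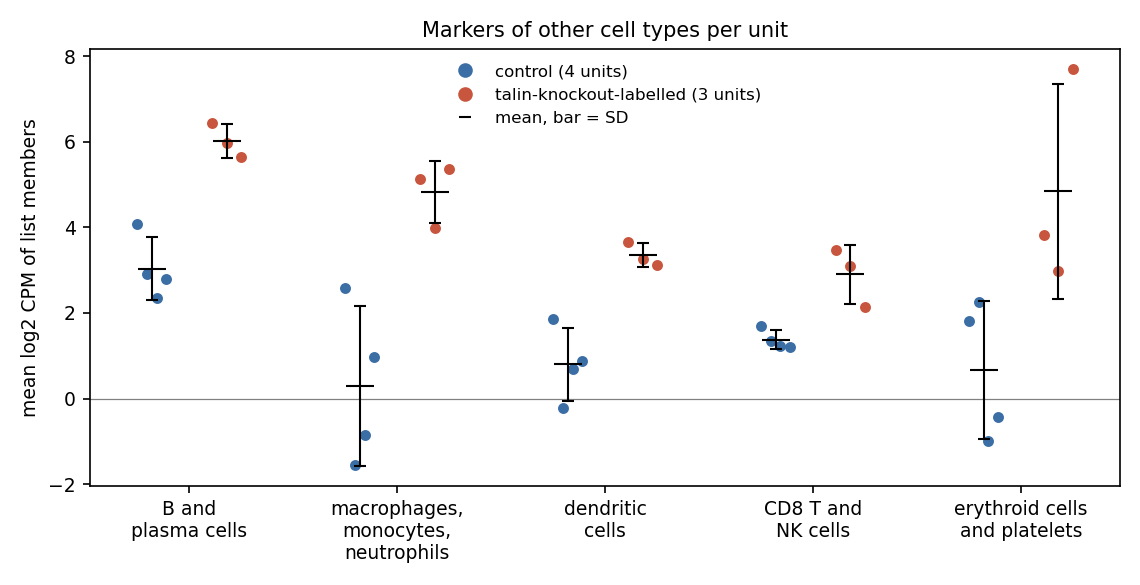
Mean log2 CPM of the members of 5 marker lists in each unit; points are units, and bars give the mean and SD of 4 control and 3 knockout-labelled units. The B cell and plasma cell means are 5.65 to 6.44 in the knockout-labelled units and 2.35 to 4.08 in the control units, of which control unit 1 is the highest.

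Of the 13 genes encoded in mitochondria, mt-Nd3, mt-Atp8 and mt-Nd6 fell and 0 rose, also adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.000367); adjusted p = 0.303 with an estimated correlation, and the median turned to 0.19 with the GC offset. mt-Atp8 passed in 6 of the 7 fits that left out 1 unit and mt-Nd6 in 1. Reads of the mitochondrial genome made up 3.25% to 4.76% of the reads of the control units and 2.75% to 4.19% of those of the knockout-labelled units. More genes had at least 1 read in the knockout-labelled units, 18741 to 19641 against 16571 to 17893. Thinned to 12851338 reads, the numbers were 17866 to 18244 against 16170 to 17334. Of the sex-linked list, Ddx3y, Uty and Kdm5d were measured. Ddx3y, a gene of the Y chromosome, averaged 0.695 CPM in the control units and 0.290 CPM in the knockout-labelled units. Uty averaged 4.13 and 2.34 CPM, and Kdm5d 56.4 and 54.6 CPM. These genes lay at widely different levels, and the sex of the animals was not determined from them.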

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

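The search for units far from the rest of their group was planned, and so was the test on further B cell and myeloid genes; the other tests given here were chosen only after the result was seen. A unit was singled out where its distance to the nearest other control unit exceeded Dixon's 95% critical share of the range of the 4 control units; the knockout-labelled group, with 3 units, was not examined. Of 157 groups of values examined, 4 stood out, while chance alone gives about 1 in 20 (5%). Klf2, which controls T cell egress, was at 326 CPM in control unit 4 and at 210 to 224 CPM in the other control units. Aurka, a mitotic kinase gene, was at 5.27 CPM in control unit 1 against 3.03 to 3.27 CPM, and Itgb1, the beta 1 integrin gene, was at 226 CPM in control unit 3 against 301 to 313 CPM. The mean of the naive and central T cell markers was 7.64 log2 CPM in control unit 1 against 7.91 to 7.96. No technical or biological explanation was tested for these 4 values.

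Cells of other types in the sorted fraction are a candidate explanation for the rise of their markers in the knockout-labelled units: 24 further B cell and myeloid genes, listed before their values were looked at, had a median log2 fold change of 2.50, all 24 lay above 0, and edgeR called 10 higher and 0 lower. Of these, 9 of 12 B cell genes and 1 of 12 myeloid genes were past the threshold. A trend on GC content and transcript length is argued against as the whole cause, since the median of the 71 genes of 4 marker lists was 3.02 before and 2.89 after the trend was taken out. The sort on Foxp3 and YFP would remove such cells if complete, Cd79a reached 52.0 CPM and Ighm 6052 CPM, and 8 of the 20 B cell and 4 of the 24 myeloid list members were at 10 CPM or more in the control units as well. RNA released by other cells stays open and was not tested. The immunoglobulin segments, which B cells express as antibody genes, held 1.02% to 2.98% of the reads of the knockout-labelled units. In the control units they held 0.0574% to 0.364%, and 50 of 192 segments rose and 0 fell. For these segments the values argue against a change in the regulatory T cells themselves, as an effect of the talin label. For the other markers such a change stays open and was not tested.

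The regulatory T cell signature fell while Foxp3 did not pass the test. If cells lacking Foxp3 had diluted every transcript of the regulatory T cells, Foxp3 would have fallen as far as the signature; with the GC offset, Foxp3 less 2 SE was at -0.71 and the signature median at -0.85, and without the offset these were -0.32 and -0.71. If Foxp3 per regulatory T cell was the same in both groups, which was not tested, this argues against dilution as the whole cause. The argument rests on 1 gene and has a small margin with the offset, and a part of the fall may still come from dilution. The trend on GC content and length is argued against too. After its removal the signature median was -0.85 and that of all genes -0.1, and 17 signature genes were called lower. An effect of the talin label on the regulatory T cells stays open; the covariate for B cell and myeloid transcripts, under which 1 signature gene fell, separated the groups and leaves little of the group difference to test.

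Of 1143 pseudogenes tested, 64 rose and 39 fell, against 1116 and 1028 of all 15775 genes, so a rise was not particular to pseudogenes; those that rose had a median of 81.6% of their sequence words shared with other genes. Reads shared with near-identical copies are a candidate explanation. Of the 64, 42 lie in sequence families with other genes and had a median log2 fold change of 5.8. The summed families had a median of -0.02. A sum also stays near 0 where a pseudogene truly rises beside a far more abundant copy. Apart from Rpl3-ps1 and Rpl3, given under the other observations, pseudogene levels were not compared with those of their copies. For the set, the sums therefore cannot tell shared reads from a real rise. Of the 37 families, 3 were past the threshold and 1 of these was higher. Whether reads went to other copies, and which difference between the groups would have sent them there, remains open. Strain variants against the reference cannot be told apart from the group: 0 of the 64 lie within 10 Mb of Tln1, where 7 of 136 genes changed, and all 14 samples carry the strain label C57/B6, but no reads were analysed here, so variants elsewhere could not be examined.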

How the results depend on the processing

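The GC offset, sequence families, protein-coding genes only, the covariate for B cell and myeloid transcripts and the fit without 2 units (control unit 1 and knockout-labelled unit 3) were chosen only after the result was seen; the other alternatives were planned. Where a result changed, the cause was not tested, except that a stricter threshold leaves fewer calls by construction. Genes past the threshold numbered 2144 (1116 higher, 1028 lower). They were 3582 (1926 higher, 1656 lower) with the DESeq2 Wald test, 450 (357 and 93) with glmTreat, 403 (254 and 149) at an FDR of 0.01, 7012 (3848 and 3164) with 14 samples as replicates and 3377 (1721 and 1656) with the unit as a random block. With the replicate number as a block, although the numbers do not pair the units, they were 612 (345 and 267). The covariate left 16 (2 and 14), and the fit without 2 units 1327, of which 441 were lower. A mean of at least 10 CPM gave 604 higher, the GC offset 713 higher and the length offset 590 lower. Leaving out 1 unit gave 758 to 1905 in all, 449 to 1120 higher and 309 to 978 lower; without control unit 2 there were 1122 (615 and 507), without control unit 4 758 (449 and 309), without knockout-labelled unit 2 1131 (722 and 409), without knockout-labelled unit 3 977 (540 and 437) and without control unit 1 686 lower. Of the genes called both here and in each of the 26 alternatives with a comparable gene set, 0 had the opposite sign. This was nearly given in advance, since the fits use the same reads. With the GC offset 1170 of 1832 calls were shared. Of the 35 splits of the 7 units into 4 and 3, 1, the real one, gave as many genes, and the highest other split gave 158. A share of 1 in 35 is the smallest that this test can reach. It makes chance an unlikely source of the count but cannot exclude it. Pathway lists past the threshold numbered 7, against 1 with an estimated correlation, 1 with fry, 12 with the GC offset and 5 to 11 leaving out 1 unit, the 11 without control unit 1. The log2 fold change of Tln1 was 0.44 and past the threshold with 14 samples as replicates and also 0.44 with the random block; it reversed to -0.37 with the length offset, to -0.11 with the GC offset and to -0.23 in limma on log2 TPM with each of 3 pseudocounts. Foxp3 reversed to -0.38 with the GC offset, -0.01 among protein-coding genes, -0.11 with the covariate, -0.02 on log2 TPM with each pseudocount, -0.07 without control unit 2 and -0.12 without knockout-labelled unit 2, within a range of -0.12 to 0.12 leaving out 1 unit. Ctla4 went to 0.01 with the length offset and to 0.02, 0.02 and 0.01 on log2 TPM with pseudocounts of 1, 0.1 and 5; Col1a1 went to 0.25 and to 0.05, 0.15 and 0.01 in the same settings. Itgal went to 0.00 with the length offset and 0.01 without 2 units. Itgb2, at 0.00, went to -0.01 with DESeq2 size factors and the Wald test, 0.00 with the second sample alone, the block and the families, -0.33 with the GC offset, -0.04 among protein-coding genes, -0.02 without 2 units and between -0.06 and 0.09 leaving out 1 unit. With the covariate Igfbp4 went to 0.18, Cd3e to 0.10, Idi1 to 0.02, Hspa5 to -0.33 and Cd44 to -0.29. Rpl3 went to 0.04 with families, and the mitochondrially encoded list turned up with the GC offset (adjusted p = 0.774). The GC offset shifted the log2 fold changes of single genes by a median of -0.20, and the median of all genes went from 0.06 to -0.1. Sign turns of values near 0 under this offset can partly reflect that shift. Over the 125 named genes other than Tln1 and their alternatives, 2996 values kept direction and side of the threshold, 564 lost the call, 122 gained it and 37 reversed. Between 12851425 and 56109143 reads per unit, levels under 0.236 CPM in the shallowest unit were not detectable.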

Other observations

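Apart from Mndal and Rpl3, which the fixed rule names, the genes in this part were chosen after their values were seen; the summing of sequence families was chosen only after the result was seen. No list of basophil or eosinophil markers was fixed in advance, and 3 single genes of these cells are given here. Mcpt8 and Prss34, which encode basophil proteases, had 2 and 1 reads in all control units and 1093 and 2192 in the knockout-labelled units. Their ratios were 335 (95% counting interval 92.5 to 2770) and 1340 (241 to 53100). These intervals rest on reads pooled over the units of a group and leave out the spread between units. Epx, the eosinophil peroxidase gene, had 5 and 1171 reads. Ccl4, a chemokine gene, rose by 6.03 ± 0.53 on the log2 scale, and Zbtb16, the gene of the innate T cell factor PLZF, rose from 0.315 ± 0.119 to 8.55 ± 5.35 CPM. Ifi202b, an interferon-inducible gene, had 0 reads in the control units and 1888 in the knockout-labelled units, while Mndal, another member of its family, had a log2 fold change of -2.03 ± 0.48; alleles at these genes were not analysed here. In total 51 genes lay under 0.5 CPM in every control unit and over 2 CPM in every knockout-labelled unit, of which 30 were protein-coding, 12 pseudogenes and 9 immunoglobulin segments, and 0 genes did the reverse.

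The pseudogene Gm15459 went from 1.51 ± 0.312 to 730 ± 148 CPM and shares 94.0% of its sequence words with other genes; Hspa8, the heat shock gene, had a log2 fold change of -0.12 ± 0.22. The pseudogene Rpl3-ps1 went from 0.297 ± 0.346 to 664 ± 217 CPM, while Rpl3, the ribosomal protein gene, went from 1287 ± 322 to 663 ± 174 CPM. For Rpl3 these values are consistent with reads moving between the gene and its copy, since the summed family had a log2 fold change of 0.04.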
